A study of Mus musculus with 2 samples.

How the data were processed

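H3K27me3 ChIP-seq was analysed in midbrain of mouse embryos at embryonic day 16.5 (strain B6NCrl, males and females pooled) in 2 biological replicates of 1 group, grouped by the tissue, antibody and age in the labels. The replicate numbers come from the labels, which name separate biological samples. Each replicate had 1 narrowPeak list, and a pooled and a replicated list belonged to the whole series. Per the labels, library fragments were selected at 300 to 500 bp and the data are on build mm10. Per the file listings deposited with the libraries, control alignments were among the sources of the peak lists, the pooled list came from the filtered alignments of both replicates and the replicated list from the pooled list and the 2 replicate lists. The 2 technical replicates of replicate 2 were combined by the authors. The aligner, the peak caller and their settings are not given in the sources used here, nor are read numbers, so the depth per sample is unknown and no interval that needs it was computed.

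The deposited columns were an integer score up to 1000, the fold enrichment (ratio) over control, −log10 p, −log10 q and the position of the summit in the peak. The authors' fold was above 1 at every peak, and the deposited −log10 p values started just above 2 in each list, so the lists reached a p-value of about 0.01. The deposited −log10 q values reached 0 in the pooled and replicated lists, so these lists were not limited by q. The deposited score and summit position were read and entered no result. Fold and −log10 values are the authors' own per peak and were used only to describe, rank or filter peaks within a list. A narrow peak caller cuts broad H3K27me3 regions into pieces, so numbers of peaks were reported beside covered bases and merged domains.

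Gene positions came from GENCODE M21 and sequence from GRCm38, the assembly of mm10. Chromosome names and lengths fitted the lists. The 21755 protein-coding genes on chromosomes 1 to 19 and X were used. A gene was called marked where a peak of the replicated list overlapped the 1 kb on both sides of its 5′ end by at least 1 bp. Coverage of a gene was the share of the 5 kb on both sides of the 5′ end under peaks, per replicate list, given as mean ± SD with n = 2. Domains were replicated peaks merged where at most 3 kb apart. CpG ratios were observed over expected CpG in the 500 bp on both sides of the 5′ end. Shares of the genome refer to known bases, without runs of N.

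Before the data were examined, 20 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of the genes listed, 1 erythroid gene (Ahsp) was not found as a protein-coding gene in the annotation, which left 13 of 14 in that list. Olfactory receptor genes were those with the prefix Olfr and a number. Each list was tested with a two-sided Fisher's exact test of marked against unmarked genes, in the list against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. The X chromosome against autosomes and the CpG classes were tested with two-sided Fisher's exact tests. Replicate overlap was compared with 100 seeded circular shifts of the replicate 2 list along each chromosome. No comparison between groups of samples exists in this design.

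The rule for named genes took, per list, up to 4 marked members with the highest coverage and up to 2 members without a promoter peak in either replicate list, in alphabetical order. It took every marked or unmarked member where these were 5 or fewer. It also took the genes of the 10 widest domains with a protein-coding 5′ end, and the 5 genes with a promoter peak of highest fold in 1 replicate and none in the other, each way. Other members named with a value were chosen after their values were seen.

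The alternatives were peaks with a −log10 q of at least 2 or a fold of at least 3, windows of 500 bp and 2.5 kb, at least 500 bp of the window covered, the pooled list, each replicate list alone, promoter peaks in both replicate lists, any of the 93196 annotated transcript starts, promoters with a CpG ratio of at least 0.6 only, and rotations of the calls along the gene order. Replicate overlap was repeated with 50% overlap of 1 or both peaks, equal numbers of peaks and merged peaks. Domains were repeated with merging gaps of 0, 1 and 5 kb. The plan had named 100000 rotations, but only 21755 distinct ones exist, and all were used, so the smallest permutation p they give is 4.6e-05.

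The promoter calls and list tests were tested on simulated peaks over the 21755 genes. All simulated marked promoters (100%) were called, 3 of 3 lists that had been raised passed, and in 4 of 100 draws without an effect any list passed. The simulated peaks were centred inside the promoter window, so the 100% was fixed in advance and checks the code alone. The draws without an effect marked genes independently, so they do not measure false passes where neighbours share domains. Overlaps were checked against bedtools 2.31.1. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.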

Results

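Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark that Polycomb repressive complex 2 places on chromatin of silenced developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain of mouse embryos of strain B6NCrl at embryonic day 16.5. The study had 1 group with 2 biological replicates, each a pool of male and female embryos, and no second tissue, age or treatment. The labels give 37 embryos for the pool of replicate 2 and 2 technical replicates for that library against 1 for replicate 1. The measurements were 4 peak lists on mouse genome build mm10: 1 per replicate, 1 called on the reads of both replicates together (the pooled list) and 1 holding those pooled peaks that the authors kept after comparison with both replicate lists (the replicated list). Read numbers are not given in the sources used here, so the depth behind each list is unknown and a missing peak is not evidence that the mark was absent. With 1 group, the comparisons were between the replicates, between parts of the genome and between groups of genes.

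The replicated list held 26635 peaks that covered 14.3 Mb, or 0.559% of the known bases of chromosomes 1 to 19 and X. The replicate 1 list was the longest, with 73159 peaks over 25 Mb, against 45228 peaks over 17.4 Mb in replicate 2 and 39003 peaks over 17.1 Mb in the pooled list. Median peak width was 240 bp in replicate 1, 258 bp in replicate 2 and 356 bp in the replicated list, whose widest peak spanned 9437 bp. Every replicated peak was also in the pooled list, 84.0% of them overlapped peaks of both replicate lists, 15.9% overlapped 1 of the lists and 29 peaks overlapped neither. No peak lay on chromosome Y in any of the 4 lists. All lists reached down to a p-value of about 0.01, and 42.7% of replicate 1 peaks, 41.8% of replicate 2 peaks and 47.6% of replicated peaks had a −log10 q of at least 2.

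The replicates shared far more of their peaks than lists placed at random. Of the replicate 2 peaks, 56.6% overlapped a replicate 1 peak by at least 1 bp, against a mean of 2.00% and a highest value of 2.93% in 100 circular shifts of the replicate 2 list along each chromosome. The overlap was 28.4 times the shifted mean, and its one-sided permutation p of 0.0099 is the smallest that 100 shifts can give. From the other side, 34.7% of replicate 1 peaks overlapped a replicate 2 peak. The bases covered in both lists made up 30.3% of those covered in either. When at least 50% of both peaks had to overlap, the share of replicate 2 peaks was 29.4%, against a shifted mean of 0.521%. With peaks at most 3 kb apart merged first, it was 49.6% against a shifted mean of 4.96%, or 10 times.

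Promoters, taken as the 1 kb on both sides of the 5′ end of each of the 21755 protein-coding genes, held 13.7% of the bases covered by the replicated list and 1.60% of the genome, an 8.56-fold excess. In the replicate lists the promoter share was 10.6% ± 1.81 (SD, n = 2). Exons held 9.50% of the covered bases and 3.37% of the genome, and introns 33.5% and 36.2%. Sequence outside promoters and protein-coding genes held 43.2% of the covered bases against 58.9% of the genome. In both replicates the promoter share, 9.30% and 11.9%, and the exon share, 6.71% and 8.92%, lay above the genomic shares. No test was run on these shares.

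A peak of the replicated list lay within 1 kb of the 5′ end of 2274 protein-coding genes, or 10.5%, and these genes are called marked from here on. The replicate lists gave 3362 and 2699 genes, a mean of 13.9% ± 2.15 (SD, n = 2). Both replicate lists had a promoter peak at 2329 genes, replicate 1 alone at 1033 and replicate 2 alone at 370, while 18023 genes had none in either list. Of the 2274 marked genes, 2123, or 93.4%, had a promoter peak in both replicates. The genes with the highest fold of a promoter peak in replicate 1 and no promoter peak in replicate 2 were Dctn3 (authors' fold 8.02), Ess2 (7.30), Ttc7 (6.62), Klhl21 (6.21) and Ier3 (6.17). Those with a promoter peak in replicate 2 and none in replicate 1 were Nfe2l3 (4.89), B830017H08Rik (4.79), Pde3a (4.76), Fignl2 (4.69) and Kcna5 (4.69). The fold is the authors' value per peak and ranks peaks only within a list. Counting only promoters with at least 500 bp covered left 1490 marked genes.

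Genes of 20 lists were compared with all other protein-coding genes to show which programmes carried the mark in this tissue. In the replicated list Hox genes and the 3 lists of brain transcription factors were marked at 83.3% to 100% of members, the dopaminergic, transmitter, oligodendrocyte and endothelial lists in part, and the pan-neuronal and housekeeping lists at no member. In the replicated list, 13 lists were marked more often than the other genes and 1 list, the olfactory receptors, less often, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 20 lists at a threshold of 0.05. Genes are not independent replicates and neighbours share domains, so these tests describe these peak lists. The same 13 and 1 lists passed when the calls were rotated along the gene order. Coverage below is the share of the 5 kb on both sides of the 5′ end under peaks, as the mean ± SD of the 2 replicate lists (n = 2).

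**Figure D1:**
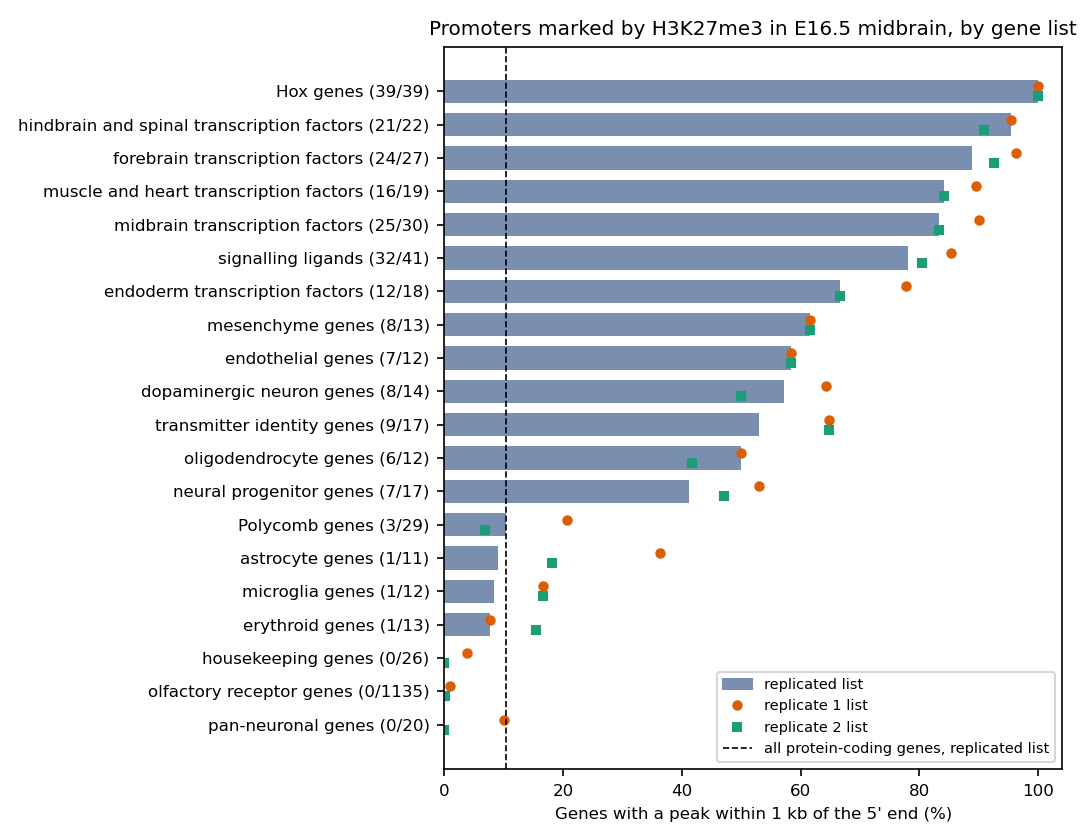
Share of genes in each of the 20 lists with a peak within 1 kb of the 5′ end, in percent, with marked and measured genes in brackets. Bars give the replicated list, circles replicate 1, squares replicate 2, and the dashed line all protein-coding genes in the replicated list (10.5%). The Hox genes stand at 100% in all 3 lists, and the pan-neuronal, housekeeping and olfactory receptor genes at 0% in the replicated list.

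All 39 Hox genes, which set position along the body axis, were marked in the replicated list and in both replicate lists (adjusted exact p = 4.2e-38 against 10.3% of other genes). Hoxc12 had the highest coverage of them, 94.2% ± 1.06, followed by Hoxb13 (93.5% ± 2.5), Hoxd11 (92.9% ± 2.28) and Hoxc4 (91.5% ± 0.339). Of 27 forebrain transcription factors, 24 were marked (adjusted exact p = 2.8e-20). Six3, a factor of the anterior forebrain and eye, had 85.6% ± 0.608 coverage, Gsx2 74.5% ± 7.49, Vax2 74.0% ± 2.89 (SD, n = 2) and Dlx1 71.7% ± 6.26. The 3 unmarked members differed: Hesx1 had no covered base, while Dlx2 had 46.4% ± 3.71 coverage and a promoter peak in both replicate lists, and Emx2 had 50.8% ± 4.02 and a promoter peak in replicate 1. Of 22 hindbrain and spinal cord factors, 21 were marked (adjusted exact p = 1.5e-19), led by Ptf1a at 83.8% ± 1.92, Mnx1 at 81.9% ± 0.113, Tlx1 at 80.4% ± 1.01 and Olig3 at 77.3% ± 7.72. The remaining member, Mafb, had 52.5% ± 8.17 coverage and a promoter peak in replicate 1.

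Transcription factors listed for the midbrain itself were marked at 25 of 30 genes (adjusted exact p = 9.1e-20). Whether the cells of this tissue used these factors at this age was not measured. With at least 500 bp of the window covered the count was 15, and with a −log10 q of at least 2 or a window of 500 bp it was 20, and the list passed in each of these settings. Foxa1 and Foxa2, factors of the floor plate and of dopaminergic neurons, had 74.4% ± 7.57 and 69.4% ± 6.79 coverage. Nkx2-2, a ventral patterning factor, had 72.0% ± 5.59 and Pax5, a factor of the midbrain-hindbrain boundary, 68.7% ± 12.1. The 5 unmarked members were En1, Lhx1, Otx2, Meis2 and Tal2. Otx2, which specifies forebrain and midbrain, had 15.1% ± 2.52 coverage, and En1, a factor of the midbrain-hindbrain region, had 38.6% ± 6.60. En1, Lhx1 (33.5% ± 7.81) and Otx2 had a promoter peak in replicate 1 alone, and Meis2 (3.99% ± 5.65) and Tal2 (9.55% ± 5.87) in neither replicate.

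Genes of neuron subtypes were marked more often than other genes. Of 14 dopaminergic neuron genes, 8 were marked (adjusted exact p = 4.3e-05). Ret, a receptor for neurotrophic factors of the GDNF family, had 39.5% ± 0.354 coverage, the dopamine transporter gene Slc6a3 39.4% ± 6.02, Dlk1 38.5% ± 4.84 and the dopamine receptor gene Drd2 29.0% ± 4.86. Aldh1a1 and Chrna6 had no covered base in either replicate. The dopamine synthesis genes Th (1.00% ± 1.41) and Ddc (0%), chosen after their values were seen, had no promoter peak in either replicate. The count fell to 4 of 14 with a −log10 q of at least 2 or with 500 bp covered and to 5 with a window of 500 bp. Over all alternatives the adjusted exact or permutation p of this list ranged from 1.9e-05 to 0.0260. The marked members Calb1 and Slc10a4, chosen after their values were seen, lay in domains of 0.334 kb and 0.350 kb. Of 17 genes that define the transmitter of a neuron, 9 were marked (adjusted exact p = 3.3e-05). The most covered were the cholinergic pair Slc18a3 (78.6% ± 6.65) and Chat (70.3% ± 3.15), which share 1 locus, the glycine transporter gene Slc6a5 (57.1% ± 0.919) and the vesicular glutamate transporter gene Slc17a7 (48.0% ± 9.50). Dbh, of noradrenaline synthesis, had 1.05% ± 1.49 coverage and Hdc, of histamine synthesis, none. Other unmarked members, chosen after their values were seen, were Gad1 (2.74% ± 1.19), Gad2 (24.0% ± 8.63), Slc17a6 (7.29% ± 10.3) and Slc6a1 (0%). Of these, Gad2 had a promoter peak in both replicate lists, Gad1 in replicate 2 and Slc17a6 in replicate 1. Slc32a1, chosen in the same way, was marked (22.3% ± 0.403). By contrast, none of 20 pan-neuronal genes was marked in the replicated list, which did not pass the test against 10.5% of other genes (adjusted exact p = 0.324). Celf4 had 1.06% ± 1.5 coverage and Elavl3 had none. Replicate 1 alone marked 2 of the 20, Nefl (15.5% ± 9.75) and Dcx (0.925% ± 1.31), both chosen after their values were seen, and replicate 2 alone marked 0.

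Of 17 neural progenitor genes, 7 were marked (adjusted exact p = 0.00145). The proneural factor genes Neurog1 and Neurog2 had 75.6% ± 0.0636 and 40.1% ± 2.39 coverage, Pax6 69.1% ± 13.0 and the Notch effector gene Hes1 32.1% ± 6.18. The radial glia gene Fabp7 and Id4 had no covered base. This list did not pass with peaks limited to a −log10 q of at least 2, where 2 members were marked (adjusted exact p = 0.488), or with a window of 500 bp (adjusted exact p = 0.0600). Over all alternatives its adjusted exact or permutation p ranged from 0.000616 to 0.488.

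Among glial lists, 6 of 12 oligodendrocyte genes were marked (adjusted exact p = 0.00105), and these included the lineage factor genes Olig1 (82.7% ± 0.566), Olig2 (55.1% ± 0.990) and Sox10 (40.1% ± 2.68) and the precursor receptor gene Pdgfra (50.1% ± 0.318). The myelin gene Mbp, chosen after its values were seen, was also marked, with 4.80% ± 3.48 coverage and a promoter peak in replicate 1 alone. The myelin genes Cnp (5.14% ± 2.62) and Mag (2.94% ± 0.537) had no promoter peak in either replicate. With a −log10 q of at least 2, 4 of the 12 were marked. Of 11 astrocyte genes only Gja1 was marked (14.8% ± 6.34), and Agt (2.79% ± 0.976) and Aldh1l1 (0%) had no promoter peak in either replicate. Replicate 1 alone marked 4 of the 11 and replicate 2 alone 2, both including Slc4a4 (12.5% ± 3.54), chosen after its values were seen. Of 12 microglia genes only C1qc was marked (29.5% ± 7.55), and Aif1 (0.930% ± 1.32) and C1qb (1.83% ± 2.59) had none. Each replicate list marked 2 of the 12, C1qc and C1qa (25.4% ± 4.26), the latter chosen after its values were seen. Of 13 erythroid genes only Epor, the erythropoietin receptor gene, was marked (42.4% ± 10.4), and Alas2 (0.925% ± 1.31) and Gata1 (0%) had none. The adjusted exact p was 1 for each of these 3 lists. The astrocyte and microglia shares lay above those of other genes in both single replicate lists and the erythroid share (2 of 13) in replicate 2, without passing.

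Endothelial genes were marked at 7 of 12 (adjusted exact p = 0.000111). The receptor gene Flt1 had 65.3% ± 5.27 coverage, and Sox18 (61.6% ± 4.62), Sox17 (52.3% ± 4.60) and Esam (43.8% ± 9.17) followed. The other 5 members, Cdh5, Emcn, Pecam1, Tek and Tie1, had no covered base within 5 kb of the 5′ end in either replicate. Mesenchyme genes were marked at 8 of 13 (adjusted exact p = 2.5e-05), led by the transcription factor genes Foxc2 (62.8% ± 2.67), Twist1 (52.2% ± 1.74) and Foxd1 (50.3% ± 1.85) and by the collagen gene Col1a1 (51.0% ± 7.90). Of the 5 unmarked members, Col3a1, Dcn, Lum and Rgs5 had no covered base, and Prrx1 had 46.4% ± 1.58 and a promoter peak in replicate 1. With 500 bp covered, 5 of the 13 mesenchyme genes were marked, and the list passed.

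Transcription factors of other germ layers and secreted signals were marked more often than other genes. The list named muscle and heart factors was marked at 16 of 19 (adjusted exact p = 3.9e-13), with Pax1 at 79.4% ± 2.72, Tbx5 at 73.4% ± 3.54, Hand1 at 69.8% ± 0.219 and Pax9 at 67.1% ± 1.73. The names of this list and of the endoderm list were set beforehand and do not mean that every member is a factor of that tissue. The 3 unmarked members were Myog (3.63% ± 5.14), with a promoter peak in replicate 1, Myf5 (1.05% ± 1.48), with one in replicate 2, and Myf6 (0%). Another myogenic factor gene, Myod1, chosen after its values were seen, was marked (58.0% ± 3.37). The list named endoderm factors was marked at 12 of 18 (adjusted exact p = 4.2e-08). Cdx2, an intestinal factor, had 89.0% ± 5.10 coverage, its neighbour Pdx1, a pancreatic factor, 82.4% ± 2.20, Nkx3-2 66.5% ± 19.2 and Foxe1 66.1% ± 3.05, while Foxi1 (0.960% ± 1.36) and Hnf1a (0.925% ± 1.31) had no promoter peak in either replicate. Signalling ligand genes were marked at 32 of 41 (adjusted exact p = 3.1e-23), led by Wnt10b (79.2% ± 7.35), Wnt1 (73.9% ± 0.757), Wnt3a (73.7% ± 1.80) and Ihh (72.9% ± 7.87). Bmp5 had no covered base, and Fgf18 had 16.4% ± 0.537 coverage without a promoter peak.

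Genes of the Polycomb machinery were marked at 3 of 29, Pcgf1 (41.2% ± 6.86), Pcgf5 (23.7% ± 12.3) and Phf19 (12.6% ± 2.22), against 10.5% of other genes (adjusted exact p = 1). Of the single replicate lists, replicate 1 alone had a promoter peak at Pcgf1. Replicate 1 alone marked 6, replicate 2 alone 2 and a window of 2.5 kb 8 of the 29, on either side of the other genes, without passing. Aebp2 and Cbx6 had no covered base. None of 26 housekeeping genes was marked (adjusted exact p = 0.139), with no covered base at Actb and 3.61% ± 5.10 at B2m. With a window of 2.5 kb this list passed as marked less often (adjusted exact p = 0.0336), and over all alternatives its adjusted exact or permutation p ranged from 0.0336 to 0.368. None of 1135 olfactory receptor genes was marked in the replicated list, against 11.0% of other genes (adjusted exact p = 4.9e-55). This comparison did not hold promoter CpG content constant, and no promoter of this list had a CpG ratio of at least 0.6. Over all genes, 2.34% of promoters with a ratio below 0.2 and 8.61% of those from 0.2 to 0.4 were marked. Olfr1 and Olfr10 were among the 1122 of them without a promoter peak in either replicate, and the replicate lists marked 0.573% ± 0.561 (SD, n = 2).

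The mark formed broad blocks over the Hox clusters. Peaks covered 86.8% ± 0.348 (SD, n = 2) of the Hoxc cluster from its first to its last gene (chromosome 15, 102921103 to 103036852), 82.9% ± 0.377 of Hoxa (chromosome 6, 52155590 to 52260880), 80.6% ± 2.22 of Hoxd (chromosome 2, 74668310 to 74765142) and 72.7% ± 0.976 of Hoxb (chromosome 11, 96194316 to 96368256). Merging replicated peaks at most 3 kb apart gave 8750 domains with a median width of 653 bp, of which 507 were at least 10 kb wide and held 43.3% of all covered bases. A protein-coding 5′ end lay in or within 1 kb of 309 of the 507 wide domains. The number of wide domains followed the merging gap, with 231 at 1 kb and none at 0 kb. In the single replicate lists it was 1004 in replicate 1 and 720 in replicate 2, among 32621 and 16700 domains.

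**Figure D2:**
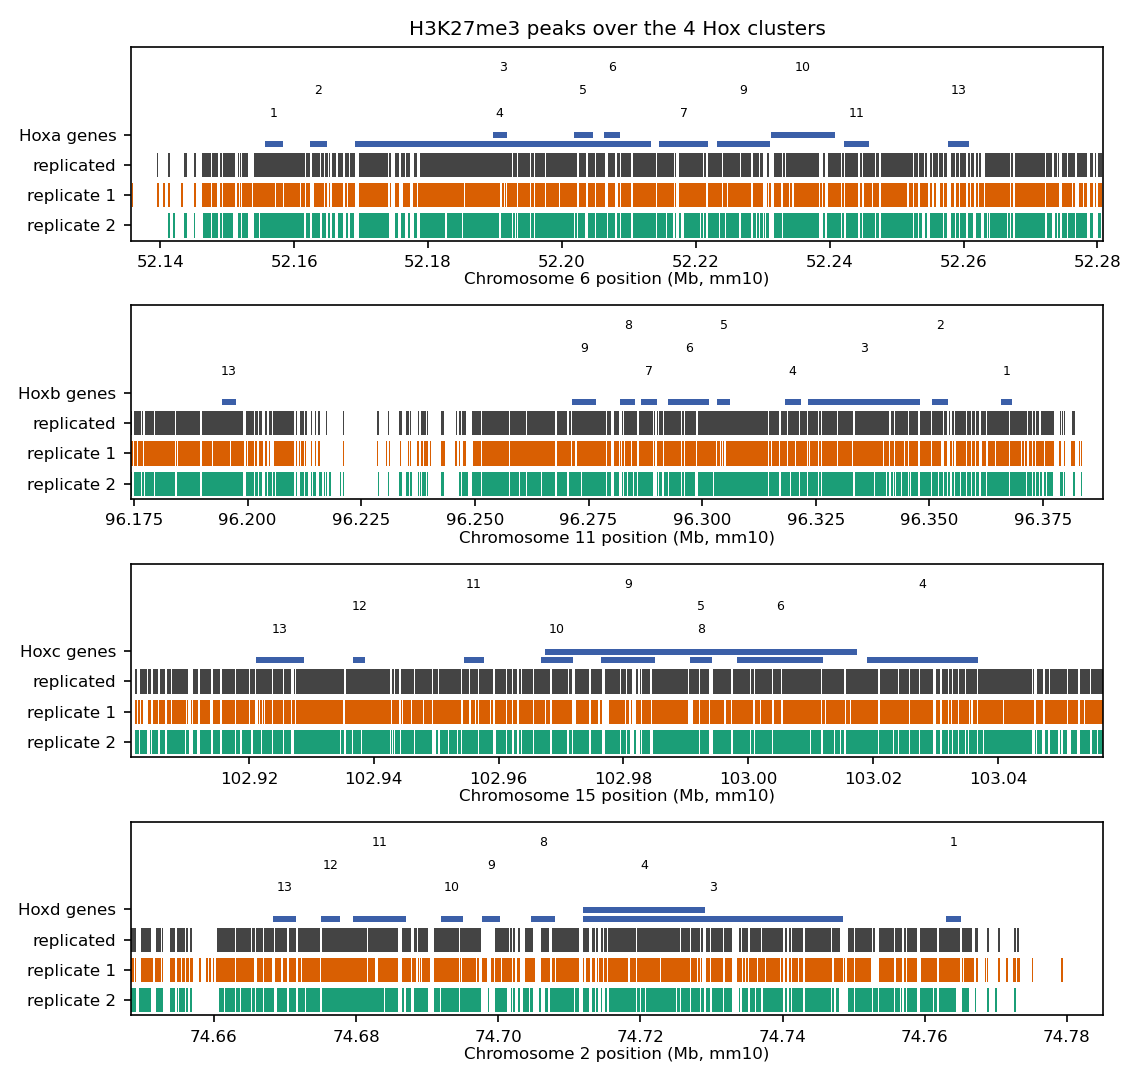
Peaks of the replicated list and of both replicate lists over the 4 Hox clusters, with genes as blue bars numbered by paralogue group, against position in Mb on mm10. Peaks cover 72.7% to 86.8% of each cluster (mean of the replicate lists), with gaps between Hoxb13 and Hoxb9 in all 3 lists.

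The widest domain, 187.5 kb on chromosome 6 (52139500 to 52327009), spanned the Hoxa cluster and Evx1 with 14 protein-coding 5′ ends. Next came Hoxc (180.0 kb, 9 genes), Hoxb1 to Hoxb9 (153.6 kb) and Hoxd with Evx2 (112.9 kb). The other domains among the 10 widest with a protein-coding 5′ end lay over 1 gene each. Pax3, a dorsal neural tube factor, lay in 88.6 kb on chromosome 1 (78133224 to 78221784), of which the replicate lists covered 54.8% ± 7.11 (SD, n = 2). Iqsec2 lay in 88.4 kb on chromosome X (152142622 to 152231015; 41.8% ± 4.61 covered) and the cardiac sodium channel gene Scn5a in 78.3 kb on chromosome 9 (119511071 to 119589377; 66.3% ± 5.57). Dmbx1, a midbrain homeobox gene, lay in 59.4 kb on chromosome 4 (115927675 to 115987058; 55.1% ± 7.42) and Tbx5 in 55.3 kb on chromosome 5 (119792016 to 119847280; 67.5% ± 2.44). The domain at Zfx, 54.1 kb on chromosome X (94121260 to 94175330; 40.6% ± 9.05), reached the gene's 5′ end without a replicated peak within 1 kb of it.

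Because the pools mixed males and females, X-linked signal came from a mixture of cells with 1 or 2 X chromosomes. Of 948 genes on X, 82 were marked, or 8.65%, against 10.5% of 20807 autosomal genes, which did not pass a two-sided Fisher's exact test (odds ratio 0.804, p = 0.0649). It passed below 1 in 6 planned settings, with odds ratios from 0.450 (−log10 q of at least 2, exact p = 5.1e-07) and 0.588 (500 bp covered, exact p = 0.000610) to 0.801 (any transcript start, exact p = 0.0409). The direction turned with a single replicate list, with odds ratios of 1.06 and 1.11. Peaks as such were denser on X than on autosomes. The replicated list had 18.7 peaks per Mb on X and 9.84 on autosomes, a ratio of 1.90, and the ratio in the replicate lists was 1.97 ± 0.0526 (SD, n = 2). In covered bases the excess of the replicated list was smaller, with 0.652% of X and 0.552% of autosomes covered, a ratio of 1.18 and rank 7 of 20 chromosomes. That ratio was 1.56 in replicate 1 and 1.41 in replicate 2. Replicated peaks on X were narrower, with a median width of 296.5 bp against 368 bp on autosomes. The excess depended on the fold of the peaks. With peaks of a fold of at least 4 in the replicated list X had 1.16 per Mb and autosomes 2.37, a ratio of 0.489. In the replicate lists that ratio was 1.66 and 1.01. With a −log10 q of at least 2 it was 1.05 in the replicated list. Both limits were chosen for this ratio after the data were seen.

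**Figure D3:**
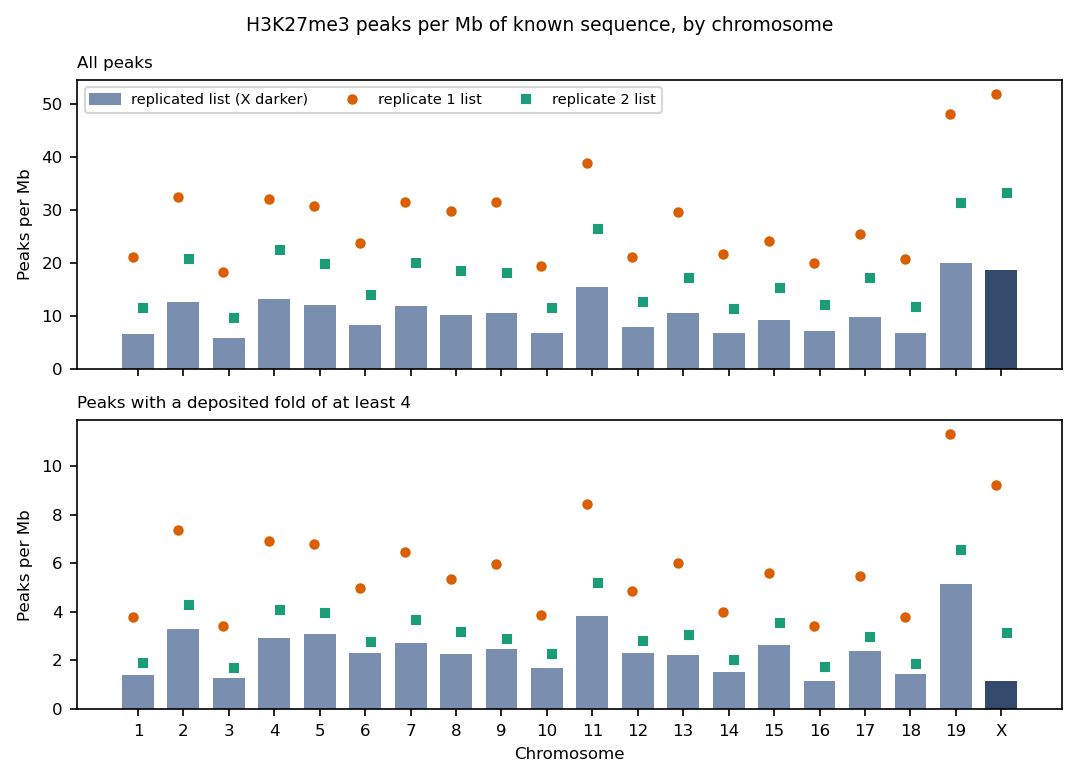
Peaks per Mb of known sequence on each chromosome, for all peaks (top) and for peaks with a deposited fold of at least 4 (bottom). Bars give the replicated list, circles replicate 1 and squares replicate 2. X has 18.7 replicated peaks per Mb, second to chromosome 19 with 20.1, and 1.16 at the higher fold.

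Promoters with an observed to expected CpG ratio of at least 0.6 in the 500 bp on both sides of the 5′ end were marked at 11.7% (1174 of 10077) and the other promoters at 9.42% (1100 of 11678). The difference was small and passed a two-sided Fisher's exact test in the replicated list (odds ratio 1.27, p = 9.4e-08). It did not pass with replicate 2 alone (odds ratio 1.05, exact p = 0.224) or with replicate 1 alone (odds ratio 1.07, exact p = 0.0740). The share of marked promoters was not ordered by CpG ratio: it was 2.34% below 0.2, 8.61% from 0.2 to 0.4, 21.8% from 0.4 to 0.6, 15.3% from 0.6 to 0.8 and 7.07% from 0.8 up. In both replicate lists, too, the class from 0.4 to 0.6 was the highest, with 30.1% and 25.4%.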

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

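The settings below were planned, except those for peaks per Mb on X, which were chosen after the result was seen. Of 335 values recomputed under an alternative, 266 were classed as unchanged. Tested values, with replicate overlap, were classed so if they kept their direction and their side of the threshold, however far they moved. Shares of covered bases and the ratio of peaks per Mb on X were classed so if they moved less than their spread. Counts were classed so within a fixed ratio of the main count, without use of a spread. The 3362 marked genes of replicate 1 thus passed as unchanged against 2274 in the replicated list. Of the 20 gene lists, 18 stayed on the same side of the threshold under every alternative that gave a value, with the neural progenitor and housekeeping lists as exceptions. No list that had passed reversed. The astrocyte, microglia, erythroid and Polycomb lists lay on either side of the other genes without passing in any setting. Astrocyte genes were above at 9.09% with a −log10 q of at least 2, a fold of at least 3, a window of 500 bp or 500 bp covered, at 18.2% with the pooled list, any transcript start or peaks in both replicates, at 27.3% with a window of 2.5 kb, and at 18.2% to 36.4% with 1 replicate left out. Microglia genes were above at 8.33% with a window of 500 bp or 500 bp covered, 16.7% with the pooled list, with peaks in both replicates or with 1 replicate left out, and 25% at 2.5 kb. Erythroid genes were above at 7.69% with a −log10 q of at least 2 or 500 bp covered, and at 15.4% with the pooled list, at 2.5 kb or with replicate 2 alone. Polycomb genes were above at 6.90% with 500 bp covered, 10.3% with a fold of at least 3, 12.5% among CpG-rich promoters, 17.2% with any transcript start, 20.7% with replicate 1 alone and 27.6% at 2.5 kb. The neural progenitor list no longer passed at 11.8% marked (−log10 q of at least 2) and 23.5% (window of 500 bp), and the housekeeping list passed at 0% marked at 2.5 kb. The number of lists below the other genes was 2 at 2.5 kb and 0 among CpG-rich promoters, where the olfactory receptor, microglia and erythroid lists had no member left and gave no value. The X odds ratio passed, below 1, with a −log10 q of at least 2 (0.450), a fold of at least 3 (0.726), windows of 500 bp (0.712) and 2.5 kb (0.749), 500 bp covered (0.588) and any transcript start (0.801), and reversed at 1.06 to 1.11 with 1 replicate left out. The ratio of peaks per Mb on X to autosomes was 1.05 with a −log10 q of at least 2, 2.30 in the pooled list, 1.93 to 2.00 with 1 replicate left out, and reversed at 0.489 with a fold of at least 4. The CpG odds ratio was 1.05 to 1.07 with 1 replicate left out and did not pass. Marked genes numbered 1490 with 500 bp covered. Domains numbered 26635 at a gap of 0 kb, 4611 with a −log10 q of at least 2 and 16700 to 32621 with 1 replicate left out, and wide domains 0 at 0 kb, 231 at 1 kb, 300 with a −log10 q of at least 2 and 720 to 1004 with 1 replicate left out, since these settings merge or hold other numbers of peaks. A −log10 q of at least 2 left 31203, 18915, 13088 and 12670 peaks in the replicate 1, replicate 2, pooled and replicated lists. With a window of 2.5 kb, which moves bases into the promoter class, promoters held 31.8% of covered bases, exons 6.58%, introns 25.5% and other sequence 36.1%. With 1 replicate left out they held 9.30% to 11.9%, 6.71% to 8.92%, 33.5% to 34.5% and 45.7% to 49.5%. Except for the wider window and the domain settings, the cause was not tested. The unknown depth limits every statement on genes without a peak, and 2 replicates give an SD of low precision.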

Other observations

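The gene family groups, the peaks ranked by p-value and the shares by quartile in this part were chosen after the data were seen, and so were 5 parts of the tests of explanations: the interval for repeated peaks on X, the density of repeated peaks on X, the limits on q and fold for X, the comparison without Evx1 and Evx2 and the adjustment over 4 comparisons. The other tests of explanations were written after the patterns and before their own results were seen. Outside the 20 lists, 2054 of 20228 genes (10.2%) were marked. They were grouped by the letters that open their symbols, with at most 1 further letter before a digit. Symbols with more letters before the digit were left out of a family, and "starting with" has this sense below. This gave 202 families of at least 15 members, of which 6 were marked more often and 4 less often than the remaining genes (two-sided Fisher's exact test, Benjamini-Hochberg over the families). The groups follow symbols alone, can hold unrelated genes and overlap in part. Neighbouring members can share a domain, as Col4a1 and Col4a2 do. These tests were not repeated with rotations of the calls and describe these peak lists. Symbols starting with Kcn, for the most part potassium channel genes, were marked at 33 of 80 (adjusted exact p = 3.5e-11), with Kcnk15 (74.0% ± 4.77 coverage, SD, n = 2) and Kcnh3 (67.2% ± 2.05) the most covered. Symbols starting with Col, mainly collagens, were marked at 20 of 42 (adjusted exact p = 4.7e-08), forkhead factors outside the lists (Fox) at 15 of 34 (adjusted exact p = 1.4e-05), integrins (Itg) at 10 of 24 (adjusted exact p = 0.00169) and symbols starting with Adamts, which mix proteases and Adamts-like genes, at 9 of 24 (adjusted exact p = 0.00901). The Adamts share was 37.5% in the replicated list, 70.8% in replicate 1 and 50% in replicate 2. The symbols starting with Htr, marked at 9 of 18 (adjusted exact p = 0.000786), mix serotonin receptors with Htra proteases. In contrast, zinc finger genes named Zfp were marked at 13 of 397 (adjusted exact p = 1.4e-05), and 331 vomeronasal receptors (Vmn; adjusted exact p = 1.4e-13), 66 symbols starting with Def, mainly defensins, and 67 histone genes (adjusted exact p = 0.0332 for both) at none. In replicates 1 and 2 the shares were 6.05% and 3.78% for Zfp, 4.48% and 1.49% for histone genes and 0% and 3.03% for Def. The Def group did not pass when split into Defb (42 genes, adjusted exact p = 0.159) and Defa (22 genes, adjusted exact p = 0.475).

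Transcription factors of the midbrain list were covered less than those of the hindbrain and spinal list. The mean was 46.7% ± 17.5 (SD over 30 genes) against 60.3% ± 14.6 (22 genes), and both replicate lists showed the lower coverage (12.2 and 15.1 points lower). Listed factors can act in more than 1 region, as En1 of the midbrain-hindbrain region and Otx2 of forebrain and midbrain do. The contrast is therefore between lists and not between regions. The difference was -13.6 points (permutation p = 0.00388, adjusted over 4 comparisons 0.00776), and -13.2 points without Evx1 and Evx2, which lie in Hox domains (permutation p = 0.00710). The contrast was taken up after the pattern was seen in these same values, and the adjustment does not cover that choice. Among promoters with a CpG ratio of at least 0.6 the difference was -16.2 points (permutation p = 0.00154), so a split at that ratio did not remove it. CpG content was not held constant within this class, where 15.3% of promoters of all genes were marked from 0.6 to 0.8 and 7.07% from 0.8 up. Promoter CpG content therefore cannot be excluded as a cause. Against forebrain factors the midbrain difference was -6.07 points over all promoters (permutation p = 0.196) and -11.2 points among the CpG-rich ones (permutation p = 0.0133, adjusted 0.0178). A candidate explanation that was not tested is loss of the mark in the cells that use these factors, since the design has no other region.

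Promoters of neuron subtype genes (the dopaminergic and transmitter lists) were marked at 17 of 31, and those of pan-neuronal genes at 0 of 20 (two-sided Fisher's exact p = 3.0e-05). The contrast was chosen after both shares were seen, and with no pan-neuronal gene marked its difference within a CpG class, 66.7 points at a ratio of at least 0.6 (8 of 12 and 0 of 12), rests on the subtype genes alone. Promoter CpG content as the whole cause of the subtype share is argued against, since among promoters of that class 5 of 7 dopaminergic and 3 of 5 transmitter genes were marked against 11.6% of the others, and no class of CpG ratio over all genes was marked above 21.8%. No biological explanation was tested, as the lists hold a mixture of cells and the design has 1 group.

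The excess of peaks on X, which was 1.05 at a −log10 q of at least 2 and turned to 0.489 at a fold of at least 4, was larger inside protein-coding gene bodies, where X had 34.8 replicated peaks per Mb and autosomes 11.4, than outside them, where the values were 12.7 and 8.74. The inside ratio divided by the outside ratio was 2.10 (95% bootstrap interval over 1 Mb bins 1.38 to 3.18). It was 2.46 and 2.19 in the replicate lists, and 2.23 (1.47 to 3.37) and 2.69 (1.61 to 4.76) in the replicated list under those limits. At the limit on q the X to autosome ratio was 1.73 inside gene bodies and 0.774 outside them. At the limit on fold these ratios were 0.869 and 0.323, so X had no excess inside gene bodies there. A shift of X signal against its control that scaled peak numbers alike inside and outside gene bodies would give about 1. In that form a uniform shift is argued against as the whole cause. Peaks are calls above a threshold, so a uniform shift of signal need not scale their numbers alike, and these lists cannot exclude it. Calls that do not repeat between replicates stay open, since 48.4% of replicate 2 peaks on X and 57.8% on autosomes overlapped replicate 1, a ratio of 0.837 with an interval of 0.737 to 0.941 around the limit of 0.8 set beforehand. As the whole excess they cannot be told apart either: replicate 2 peaks that replicate 1 overlapped were denser on X by a ratio of 1.68, with an interval of 1.04 to 2.52. That interval holds 1.06, the ratio expected if repeated peaks beyond chance overlap were equally dense on X and autosomes. The chance overlap was taken from 100 circular shifts. Chromatin of the inactive X in female embryos may contribute and cannot be told apart here: the ratio of 2.10 is on the side it predicts, but the escape genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x had no covered base in their bodies, as did 68.1% of the other 944 X genes, so that part of the test was void.

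Of the replicate 1 peaks in the lowest quartile of −log10 p, 16.8% overlapped a replicate 2 peak, against 68.5% in the highest quartile. The corresponding shares of replicate 2 peaks were 38.8% and 86.4%. The peak with the highest −log10 p of the replicated list (32.4) had an authors' fold of 2.12, far below the 10.6 of the next, which lay 1.17 kb from the 5′ end of Klf14. It lay on chromosome 17 (39843097 to 39846543), 105.7 kb from the nearest protein-coding 5′ end, and whether reads from repeated sequence raised it was not tested. The highest −log10 p of replicate 1 (49.5, fold 2.58) lay at the same site, with another high value close by (42.1, fold 2.39). The highest of replicate 2 (33.5, fold 10.8) lay on chromosome 2. Of the 507 domains of at least 10 kb, 198 had no protein-coding 5′ end within 1 kb. Of the 15 widest domains, 3 had no protein-coding 5′ end within 1 kb: 62.9 kb on chromosome X (103679457 to 103742394) overlapping part of the gene body of Slc16a2, 52.1 kb on chromosome 5 (101507892 to 101559953) 105.0 kb from Nkx6-1, and 50.2 kb on chromosome 17 (85445013 to 85495231) overlapping the gene body of Camkmt, 118.4 kb from Six3.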
